A study of Homo sapiens with 6 samples.

How the data were processed

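The series measured RNA in TC28a2 cells, an immortalised human chondrocyte line, 48 h after transfection with a control vector or with a vector that overexpresses the transcription factor ZEB1. Each vector had 3 libraries, numbered as replicates 1 to 3 in the labels. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Libraries were made by DRUG-seq, a high-throughput, low-cost form of RNA-seq, from TRIzol-extracted total RNA, and were sequenced on a NextSeq instrument, per the labels' protocols.

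The authors deposited a table of raw counts per gene, with 28395 Entrez gene IDs in rows and the 6 libraries in columns. HISAT2, Subread, featureCounts and the build GRCh38 are named without versions in the submitters' processing notes. Whether molecular identifiers were collapsed, which strand setting was used and which annotation release was counted are not given in the sources used here. If reads were not collapsed to molecules they are not independent, and counting intervals and floors, which assume that they are, understate the error. They also leave out the spread between libraries. Gene names came from an NCBI RefSeq table of assembly GRCh38.p14, which matched 27745 IDs and left 650 unmatched. The deposited table held 0 genes of the mitochondrial genome, and 10076 genes had no count in any library.

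Total counts were 5832751, 5359200 and 5878640 in control replicates 1, 2 and 3 and 1277632, 1621270 and 3316228 in ZEB1 replicates 1, 2 and 3. A floor of 3 counts stood for 0.510 to 0.560 CPM (counts scaled to a common library total) in the controls and 2.35, 1.85 and 0.905 CPM in ZEB1 replicates 1, 2 and 3. The median standard error of a log2 fold change was 0.33 over all tested genes and 0.22 over the 5631 genes with a mean count of at least 100.

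The counts were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood test with robust dispersions, TMM factors, the filterByExpr filter and group as the only term. All p-values are two-sided, and the Benjamini-Hochberg threshold was an adjusted p of 0.05 over the 11329 genes that passed the filter. Standard errors of log2 fold changes were taken from the fold change and its F statistic and are approximate. CPM values were scaled by TMM, and a prior count of 2 was used for log2 CPM. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, on lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry were run beside it. A list score is the mean log2 CPM of its tested genes, each relative to its mean in the control libraries.

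The design, the 27 gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. The lists were written from general knowledge, not chosen on these samples, and 931 of their 961 entries were found in the table. The rule names ZEB1 and up to 12 called genes in each direction, or, where fewer than 5 genes pass, the 10 genes with the smallest unadjusted p, as values. From each list it adds up to 3 called members, or the members with the highest mean count until 2 are named. List members that passed when adjusted over the list alone, where a list had 5 or fewer of them, were named after their values were seen. Some genes that the rule names are not reported here.

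That set held RLE and upper-quartile factors, library size alone, no filter on low counts, a mean count of at least 20, thinning of all libraries to 1277632 counts, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, other thresholds, dispersions without robust estimation, an estimated inter-gene correlation and fry. Added after seeing the data were limma-voom with sample quality weights, ZEB1 left out of the table, leaving out ZEB1 replicates 1 and 2 together, and removal of each library's trends with transcript length, GC content and abundance. Transcript lengths and GC content came from GENCODE v29.

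The steps were tested on simulated counts for this comparison with 200 changed genes, drawn from those with a mean count of at least 20. The dispersion of each gene was equal in all libraries. The edgeR test recovered 44% of genes changed 2-fold among 10971 tested, 80.5% of those changed 4-fold among 10986 and 91.5% of those changed 8-fold among 10971. It made 2, 5 and 12 false calls in these runs, and recovery of changed genes with fewer counts was not tested. With no gene changed it made 0 calls among 10958 genes. With no gene changed and a wider spread in the ZEB1 libraries, edgeR, DESeq2 and both forms of limma-voom made 0 calls on 11329 simulated genes. Genes were drawn independently there, with a common dispersion within each group. The run thus does not show how many calls are false where genes vary together.

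Of the 71 named genes, 42 are overlapped in the RefSeq table by another annotated gene and 12 by another tested gene. The overlap was taken between whole gene spans on either strand, so such pairs need not share counted sequence. Where they do, reads cannot be told apart without a stated strand setting. Figures were drawn with matplotlib 3.10.9.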

Results

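TC28a2 chondrocytes carrying a control vector were compared with TC28a2 cells carrying a ZEB1 overexpression vector, 3 libraries each, 48 h after transfection. The comparison addresses which transcripts respond to ZEB1, a zinc finger repressor known from epithelial to mesenchymal transition, in a study of senescent cells in osteoarthritic cartilage and meniscus. The control libraries held 5359200 to 5878640 counts and 15010 to 15302 genes with a count. The ZEB1 libraries were shallower, with 1277632, 1621270 and 3316228 counts and 12177, 13008 and 14006 genes with a count in replicates 1, 2 and 3.

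In the edgeR test ZEB1 was the transcript that changed, while DESeq2, which adjusted over fewer genes, called 201 genes and limma-voom 22. ZEB1 rose from 24.9 ± 6.64 CPM (SD, n = 3) in the controls to 11069 ± 3724 CPM (SD, n = 3) with the ZEB1 vector, 444-fold higher. Ribosomal protein, respiratory chain and histone mRNAs were shifted higher as groups, and secretory, mesenchymal, collagen, immediate early and protease mRNAs lower. These group shifts passed a list test with a preset gene correlation and did not pass with an estimated one.

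ZEB1 (Entrez 6935, chromosome 10, 31318417 to 31529804, GRCh38.p14) had 203, 114 and 131 counts in control replicates 1, 2 and 3. The ZEB1 vector libraries held 13805, 21844 and 23143 ZEB1 counts, which was 1.08%, 1.35% and 0.698% of their totals. The log2 fold change was 8.79 (SE 0.31) with an edgeR adjusted p of 2.37e-13, and all 3 ZEB1 libraries lay above all 3 controls. Counts from the vector and from the endogenous gene were not separated.

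**Figure D1:**
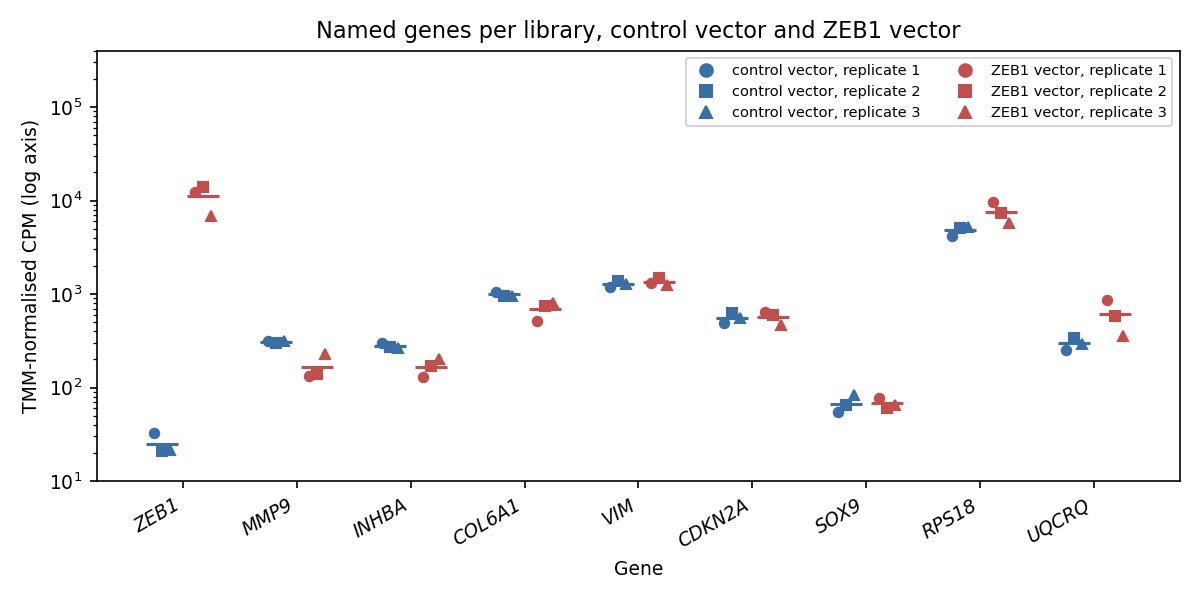
TMM-normalised CPM of 9 genes on a log axis, with 1 point per library and a bar at the mean of each group of 3. ZEB1 lies at 24.9 CPM on average in the control libraries and at 11069 CPM in the ZEB1 libraries, while VIM, CDKN2A and SOX9 overlap between the groups.

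Of 11329 genes tested, 1 passed an edgeR adjusted p of 0.05, and the next smallest adjusted p was 0.150. At an unadjusted p under 0.05 there were 1065 genes, 660 higher and 405 lower, where 566 are expected by chance. With library size as the only scaling, which moved the median log2 fold change of all genes by -0.13, this split was 347 higher and 807 lower. In 1712 genes, 15.1% of those tested, the 3 ZEB1 libraries all lay above (788 genes) or all below (924 genes) the 3 controls, where chance gives 10%. The count of genes past the threshold depended on the tool and on ZEB1 replicate 3. DESeq2 called 201 genes, limma-voom 22, and limma-voom with quality weights, added after seeing the data, 157. Without a filter on low counts edgeR called 127 genes, and without ZEB1 replicate 3 it called 409.

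The 10 genes with the smallest unadjusted p are given as values. MMP9, a gelatinase that degrades cartilage matrix, had 309 ± 8.77 CPM (SD, n = 3) in the controls and 167 ± 53.7 CPM (SD, n = 3) with the ZEB1 vector, a log2 fold change of -0.87 (SE 0.18). The respiratory chain genes NDUFB6 and UQCRQ had log2 fold changes of 0.94 (SE 0.19) and 1.03 (SE 0.22). ITGAE, an integrin alpha chain whose locus also holds HASPIN, had 1.04 (SE 0.19), and R3HDM2 had -1.84 (SE 0.37). GALT, an enzyme of galactose metabolism, had 74, 33 and 32 counts in the controls and 0, 0 and 1 with the ZEB1 vector. The ratio of its summed counts per total was 50.6 in favour of the controls, with an exact 95% counting interval of 8.93 to 2013. That interval treats reads as independent and leaves out the spread between libraries, so it is too narrow. RPL21P28, RPL23P8 and RPL26L1 had log2 fold changes of 0.86, 0.83 and 0.77, but have near-identical copies in the genome, and how the counting assigned such reads is not stated, so these values are uncertain. The edgeR adjusted p was 0.150 for ITGAE and 0.161 for the other 8 of these genes. Of these 9, DESeq2 called ITGAE, NDUFB6, RPL21P28, RPL23P8, RPL26L1 and MMP9.

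Of the 27 gene lists, 24 had enough tested members, and 8 passed camera at the preset correlation, 3 higher and 5 lower. With an estimated correlation 0 of the 24 passed camera, and fry called 1. The 4 lists with an unadjusted p under 0.05 in that camera test were the mesenchymal, protease, secretory and immediate early lists. Their estimated correlations were -0.014, -0.015, 0.037 and 0.029. The mesenchymal and protease estimates lay below the preset 0.01, so a higher gene correlation is not what cost these lists the call. With an estimated correlation camera also tests on the few residual degrees of freedom of the 6 libraries, which makes it stricter. The unadjusted camera p of the mesenchymal list was 0.000128 at the preset correlation and 0.0123 with the estimated one. A call lost in that test is thus not by itself evidence that the genes of a list vary together. No member of any list passed the edgeR threshold over all genes.

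Ribosomal protein mRNAs were higher in 76 of 78 genes, with a median log2 fold change of 0.49 (0.30 to 0.62 on leaving out single libraries). Adjusted over the list alone, 48 of the 78 passed, among them RPS18, which had 4816 ± 596 CPM in the controls and 7529 ± 1967 CPM with the ZEB1 vector (SD, n = 3, log2 fold change 0.64). RPLP1, a protein of the ribosomal stalk, had a log2 fold change of 0.41. Nuclear-encoded respiratory chain mRNAs were higher in 58 of 69 genes with a median of 0.50 (0.33 to 0.65 on leaving out single libraries), and 44 passed adjusted over the list alone. NDUFB9 and COX4I1, subunits of complexes I and IV, had log2 fold changes of 0.40 and 0.19. Both lists lost the call with an estimated correlation (adjusted p = 0.362 for each). The estimates were 0.82 for ribosomal proteins and 0.52 for the respiratory chain, far above the preset value. Genes within each list thus varied together, so the 48 and 44 genes that passed are not that many independent results. The scores of ZEB1 replicates 1, 2 and 3 were 0.77, 0.43 and 0.16 for ribosomal proteins and 0.72, 0.46 and 0.12 for the respiratory chain. The controls spanned -0.14 to 0.11 and -0.13 to 0.15, and the 2 higher scores came from the libraries with 1277632 and 1621270 counts. Those libraries also had more ZEB1, 12267 and 14047 CPM against 6894 CPM in replicate 3. Depth and ZEB1 level cannot be told apart here. Ribosomal protein genes took 24.3%, 20.9% and 18.3% of the counts in ZEB1 replicates 1, 2 and 3 and 15.9% to 18.2% in the controls.

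Replication-dependent histone mRNAs, which encode the histones made in S phase, were higher in 13 of 18 genes with a median log2 fold change of 0.41 (adjusted p = 0.362 with an estimated correlation). The median was 0.21 to 0.58 on leaving out single libraries, with 0.21 without ZEB1 replicate 1. H4C3 had 2417 ± 175 CPM in the controls and 4308 ± 1512 CPM with the ZEB1 vector (SD, n = 3, log2 fold change 0.83), and H1-2 had 0.57. Adjusted over the list alone 4 passed, H4C3, H1-2, H2AC20 (0.76) and H1-5 (0.53), but how the counting assigned reads of such similar genes is not stated, so these values are uncertain. The score of ZEB1 replicate 3 was -0.20, below the controls, while replicates 1 and 2 scored 0.36 and 0.31. The list did not pass camera without ZEB1 replicate 1 (adjusted p = 0.0585).

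Senescence-associated secretory mRNAs were lower in 26 of 33 genes with a median log2 fold change of -0.44 (adjusted p = 0.212 with an estimated correlation), and -0.54 to -0.28 on leaving out single libraries. INHBA, the activin A subunit, had 279 ± 20.5 CPM in the controls and 167 ± 36.0 CPM with the ZEB1 vector (SD, n = 3, log2 fold change -0.73). It passed adjusted over the list alone, as did the angiogenic factors ANGPTL4 (-1.10) and VEGFA (-0.60). Scores were -0.39, -0.67 and -0.25 in ZEB1 replicates 1, 2 and 3, against -0.09 to 0.10 in the controls.

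Mesenchymal mRNAs were lower in 22 of 29 genes with a median log2 fold change of -0.24 (-0.32 to -0.17 on leaving out single libraries). This list lost its camera call with an estimated correlation (adjusted p = 0.212) and was the list that fry called (adjusted p = 0.0179). Its scores were -0.27, -0.26 and -0.24 in ZEB1 replicates 1, 2 and 3, against -0.06 to 0.08 in the controls. Adjusted over the list alone 0 passed in edgeR, with 1 member higher and 7 lower at an unadjusted p under 0.05. The intermediate filament gene VIM had 1289 ± 96.5 CPM in the controls and 1356 ± 119 CPM with the ZEB1 vector (SD, n = 3, log2 fold change 0.07), and the tropomyosin gene TPM2 had a log2 fold change of -0.23. Epithelial junction and polarity genes, which include targets that ZEB1 is known to repress, had 12 of 45 members tested, 7 higher and 5 lower, with a median of 0.31. This median did not keep its sign, with -0.09 to 0.31 on leaving out single libraries, -0.03 with thinning, -0.07 with no low-count filter and -0.04 at a mean count of at least 20. The list did not pass camera (adjusted p = 0.399), and KRT18 and KRT8 had log2 fold changes of -0.07 and -0.03. CDH1, named after its counts were seen, had 0, 4 and 5 counts in the controls and 0 in each ZEB1 library, so that a change in it was not detectable at this depth.

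Fibrillar and fibrosis-linked collagen mRNAs were lower in 19 of 23 genes with a median of -0.21 (adjusted p = 0.362 with an estimated correlation), and -0.34 to -0.15 on leaving out single libraries. COL6A1 had 991 ± 55.2 CPM in the controls and 688 ± 153 CPM with the ZEB1 vector (SD, n = 3, log2 fold change -0.52), and COL6A2, also of collagen VI, had a log2 fold change of -0.48. Adjusted over the list alone 3 passed, COL6A1, COL6A3 (-0.57) and the anchoring fibril gene COL7A1 (-0.57). The score of ZEB1 replicate 3, -0.03, lay within the control range, and those of replicates 1 and 2 were -0.75 and -0.36. The list did not pass camera without ZEB1 replicate 1 (adjusted p = 0.0585). Matrix-degrading proteases and their inhibitors were lower in 15 of 22 genes with a median of -0.35 (adjusted p = 0.212 with an estimated correlation), and -0.35 to -0.21 on leaving out single libraries. MMP9 passed adjusted over the list alone, and the inhibitor TIMP1 had a log2 fold change of -0.13 (SE 0.15). Scores were -0.58, -0.39 and -0.19 in ZEB1 replicates 1, 2 and 3, and the list did not pass without ZEB1 replicate 2 (adjusted p = 0.0599).

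Immediate early mRNAs were lower in 19 of 25 genes with a median of -0.28 (adjusted p = 0.212 with an estimated correlation), and -0.45 to -0.25 on leaving out single libraries. Adjusted over the list alone 3 passed, the AP-1 genes FOSL1 (-0.66) and FOSL2 (-1.18) and the ERK phosphatase DUSP6 (-0.64), while the survival factor MCL1 had a log2 fold change of -0.10. Scores were -0.79, -0.59 and -0.18 in ZEB1 replicates 1, 2 and 3, against -0.07 to 0.09 in the controls.

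**Figure D2:**
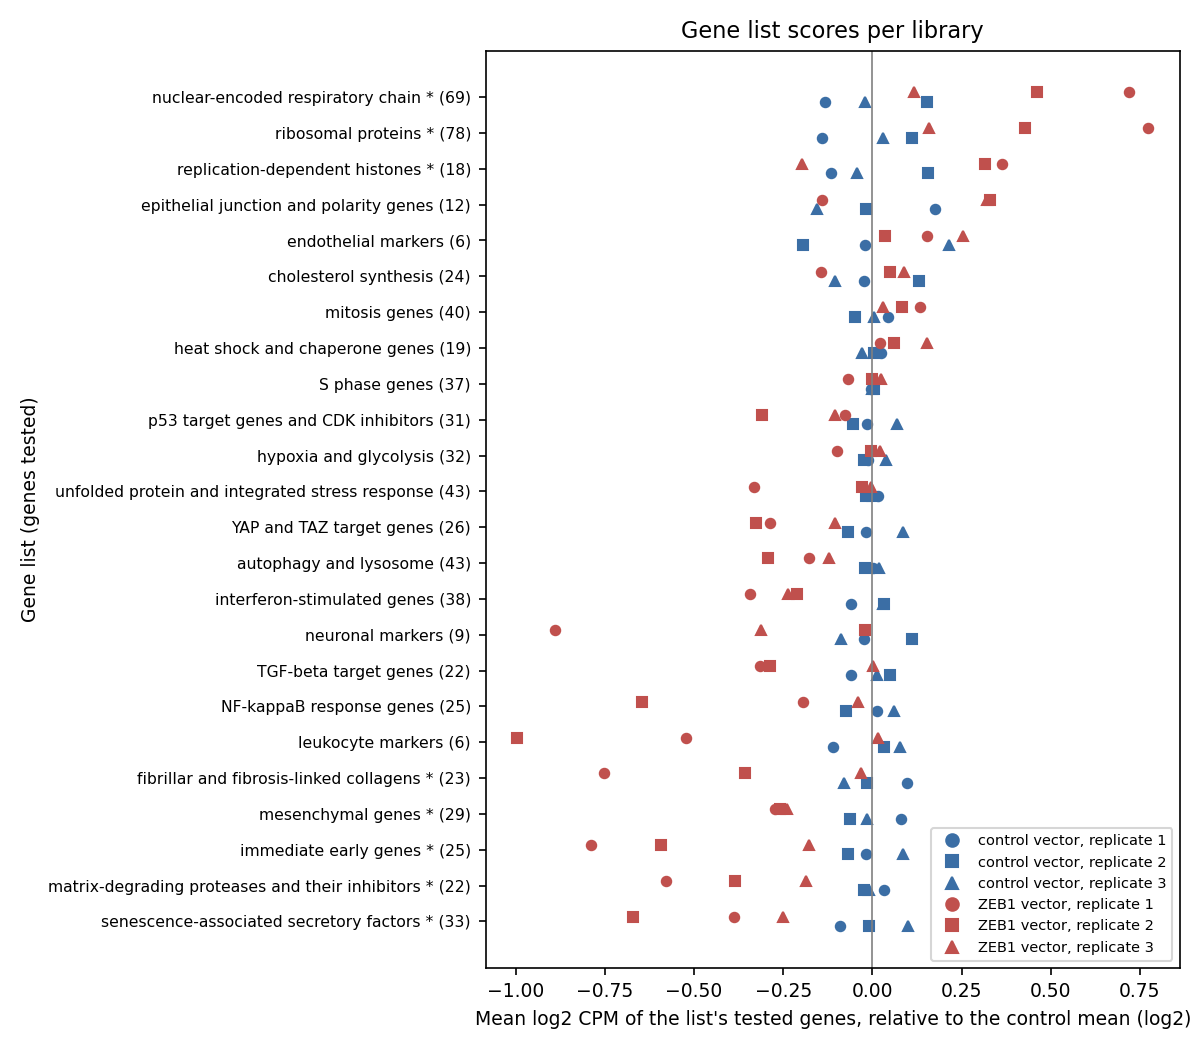
Scores of the 24 tested gene lists in each library, as mean log2 CPM relative to the control mean, with lists in order of their median log2 fold change, the number of genes tested in parentheses and an asterisk where camera passed at the preset correlation. The ZEB1 libraries reach 0.77 for ribosomal proteins and -0.67 for secretory factors, and ZEB1 replicate 3 lies nearest to the controls in both.

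The remaining 16 tested lists did not pass camera. The p53 targets and CDK inhibitors had a median of -0.04 (adjusted p = 0.378), or -0.31 to -0.046 on leaving out single libraries. Among them CDKN2A, which encodes the senescence marker p16, had 560 ± 70.3 CPM in the controls and 568 ± 88.8 CPM with the ZEB1 vector (SD, n = 3, log2 fold change 0.02). Adjusted over this list alone 2 passed in opposite directions, RPS27L (0.86) and CDKN1A (-0.68), which encodes p21. NF-kappaB response genes had a median of -0.18 (adjusted p = 0.0659), with IER3 at -0.55 and NFKBIA at -0.27. This list passed without ZEB1 replicate 3 (adjusted p = 0.0204), without control replicate 2 (adjusted p = 0.0312) and with thinning (adjusted p = 0.0367). It also passed with no low-count filter (adjusted p = 0.0345) and with quality weights (adjusted p = 0.0412). It did not pass with an estimated correlation (adjusted p = 0.483) or with fry (adjusted p = 0.261). Its scores were -0.19, -0.65 and -0.04 in ZEB1 replicates 1, 2 and 3, and without replicate 2 its median was 0.015 (adjusted p = 0.668). Mitosis genes had a median of 0.08, or -0.05 with library size as the only scaling (adjusted p = 0.0783 and 0.426). They passed without control replicate 1 (adjusted p = 0.0384) and in the list test on log2 CPM, added after seeing the data (adjusted p = 0.0494). TOP2A and UBE2C of this list had log2 fold changes of 0.06 and 0.20, and CKS2 (0.67) passed adjusted over the list alone.

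S phase genes had a median of 0.01, or -0.11 with library size as the only scaling (adjusted p = 0.701 and 0.851), with MCM7 at -0.05 and CLSPN at -0.08. Hypoxia and glycolysis genes had a median of -0.07 and a mean of -0.01 (adjusted p = 0.913), with GAPDH at 0.01, or -0.13 with library size as the only scaling, and PKM at -0.10. BNIP3 (0.73) and VEGFA passed adjusted over that list alone, in opposite directions. Heat shock and chaperone genes had a median of 0.03 (adjusted p = 0.314), with HSP90AA1 at 0.09, HSP90AB1 at -0.33 and the mitochondrial chaperonin gene HSPE1 at 0.74, which passed adjusted over the list alone. Cholesterol synthesis genes had a median of 0.09 (adjusted p = 0.310), with FDFT1 at 0.14. TGF-beta targets had a median of -0.17 (adjusted p = 0.314), or -0.25 to -0.0016 on leaving out single libraries. PMEPA1 was at -0.28 and TGFBI at -0.13. YAP and TAZ targets had a median of -0.10 (adjusted p = 0.116), with AXL at -0.24 and ASAP1 at -0.08. Interferon-stimulated genes had a median of -0.16 (adjusted p = 0.166), with B2M at 0.33 and IFITM3 at -0.12. The unfolded protein response list had a median of -0.08 (adjusted p = 0.349), with CALR at -0.25 and HSP90B1 at 0.04, and the autophagy and lysosome list -0.12 (adjusted p = 0.310), with SQSTM1 at -0.26 and LAMP1 at -0.12.

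Of the 33 cartilage matrix and chondrocyte identity genes, 4 had enough counts to be tested. SOX9, the chondrocyte transcription factor, had 67.3 ± 14.5 CPM in the controls and 68.3 ± 8.88 CPM with the ZEB1 vector (SD, n = 3), and the proteoglycan gene BGN had a log2 fold change of -0.39. ACAN and COL2A1, named after their counts were seen, had 13 and 11 counts over all 6 libraries. Hypertrophy and mineralization genes also had 4 tested members, among them RUNX3 (-0.49) and ANKH (0.30). Markers of other cell types did not pass camera. The medians were -0.20 for 6 leukocyte markers (adjusted p = 0.463), 0.20 for 6 endothelial markers (adjusted p = 0.492) and -0.16 for 9 neuronal markers (adjusted p = 0.338). On leaving out single libraries the medians of these lists were -0.59 to -0.20, 0.0073 to 0.32 and -0.28 to -0.013. Their most abundant members were SRGN (0.38) and LAPTM5 (-0.56), EGFL7 (0.12) and ENG (-0.15), and UCHL1 (0.02) and TUBB3 (-0.16).

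The spread within the ZEB1 group was wider than in the controls, with an edgeR biological coefficient of variation of 34.4% against 18.8%. The chi-square per degree of freedom of the counts of library pairs overlapped between the groups. It was 6.51, 12.2 and 9.12 for the ZEB1 pairs and 9.22, 7.60 and 7.76 for the control pairs. Whether the wider coefficient is biological or follows from the lower depth was not tested. In log2 CPM, ZEB1 replicate 3 correlated with the controls at 0.948 to 0.951 and with the shallower ZEB1 replicates 1 and 2 at 0.875 and 0.899, which correlated with each other at 0.854. The ZEB1 libraries differed from the controls in both depth and vector, so the comparison does not separate them.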

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

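Tests added after seeing the data were limma-voom with quality weights, ZEB1 left out of the table, leaving out ZEB1 replicates 1 and 2 together, and the list tests on log2 CPM with and without trend removal. ZEB1 kept its direction and its call in 18 of 18 alternatives, with log2 fold changes of 8.10 to 9.03 and adjusted p-values up to 0.000837. The count of changed genes, 1, was the same with other scaling factors, a mean count of at least 20, thinning, other thresholds and dispersions without robust estimation. It was 127 with no low-count filter, 201 with DESeq2, which gave 1982 genes an adjusted p, 22 with limma-voom, 157 with limma-voom and quality weights, 0 with ZEB1 left out of the table, where edgeR had 1065 genes at an unadjusted p under 0.05, and 2 without ZEB1 replicates 1 and 2. That setting leaves 1 ZEB1 library, which is assumed to vary like the controls, so its calls lost or gained are not read as dependence on those libraries. Leaving out single libraries gave 1 to 409, with 409 without ZEB1 replicate 3 (290 higher, 119 lower) and 1 otherwise. Of the 201 DESeq2 calls, 185 were higher, 69 were ribosomal protein or respiratory chain genes, and 181 were among the 409. The share of ribosomal protein and respiratory chain genes among all genes that DESeq2 adjusted over was not computed. The count with ZEB1 left out follows from its construction, and for the other settings the cause was not tested. The replicate block gave 1 gene and 8 lists, as without it. Deviations of same-numbered libraries from their group means correlated at -0.032, -0.0095 and 0.0087, and no library correlated best with its own number. Correlations over all numbers were small, -0.048 to 0.046, so a shared day or culture is not excluded. The planned scaling without mitochondrial genes was not run, because the table held 0 of them.

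The count of 8 lists was 0 with an estimated correlation, 1 with fry, 4 without ZEB1 replicates 1 and 2, 6 to 9 on leaving out single libraries, and 7 to 9 in the other alternatives. The test with an estimated correlation also has fewer degrees of freedom, and otherwise the causes were not tested. With the 3 trends removed together, collagens (adjusted p = 0.106, median -0.33 before and -0.32 after) and immediate early genes (adjusted p = 0.159, median -0.43 before and -0.34 after) did not pass, while endothelial markers did (adjusted p = 0.0402). The 8 lists kept their directions with RLE, upper-quartile and library-size scaling. Without ZEB1 replicates 1 and 2 their medians were 0.13 for ribosomal proteins, 0.12 for the respiratory chain, 0.072 for histones, -0.28 for secretory, -0.25 for mesenchymal, -0.14 for collagen, -0.23 for immediate early and -0.076 for protease mRNAs.

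Signs turned for named genes that had not passed, and the cause was not tested. With library size alone the log2 fold changes were VIM -0.062, SOX9 -0.12, CDKN2A -0.13, TOP2A -0.072, HSP90B1 -0.093, HSP90AA1 -0.043, GAPDH -0.13 and UCHL1 -0.11. With no low-count filter they were SOX9 -0.010, CDKN2A -0.0090, GAPDH -0.011 and UCHL1 -0.0043. With thinning KRT8 had 0.017, with limma-voom CDKN2A had -0.0016, and with quality weights SOX9 had -0.0062. On leaving out single libraries the values spanned 0 for SOX9 (-0.13 to 0.19), CDKN2A (-0.080 to 0.13), GAPDH (-0.050 to 0.051), EGFL7 (-0.045 to 0.32), UCHL1 (-0.013 to 0.066), KRT8 (-0.10 to 0.035), HSP90B1 (-0.038 to 0.11), ASAP1 (-0.18 to 0.044), MCM7 (-0.12 to 0.036), CLSPN (-0.21 to 0.043), VIM (-0.0046 to 0.13), TUBB3 (-0.34 to 0.058), HSP90AA1 (-0.012 to 0.15) and MCL1 (-0.17 to 0.0042). Without ZEB1 replicates 1 and 2 they were KRT18 0.055, KRT8 0.044, VIM -0.037, SOX9 -0.045, CDKN2A -0.27, MCM7 0.055, CLSPN 0.11, ASAP1 0.0089, B2M -0.029, NFKBIA 0.067, GAPDH -0.018, PKM 0.033, COX4I1 -0.067, LAMP1 0.13, SRGN -0.042, UCHL1 -0.022 and TUBB3 0.099. The test direction of lists that had not passed also turned, with these median log2 fold changes. S phase genes had -0.11 with library size alone, 0.029 with thinning, -0.068 to 0.065 on leaving out single libraries and -0.13 with the 3 trends removed. Epithelial genes had -0.036 at a mean count of at least 20. Hypoxia and glycolysis genes had -0.075 with the replicate block, -0.078 to -0.048 on leaving out single libraries, -0.073 on log2 CPM and -0.019 without ZEB1 replicates 1 and 2. In that last setting TGF-beta targets had 0.056 and NF-kappaB response genes 0.035. With the 3 trends removed mitosis genes had -0.12 and heat shock genes -0.12. The other values for named genes kept their sign, and 94 of them, each outside the threshold before, passed under an alternative.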

Other observations

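The 9 groups in the next paragraph were chosen after the data were seen, as were the tests of joint trends, of ZEB1 replicate 3 for ribosomal and respiratory chain genes, and of read clumping.

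Mitochondrial ribosomal protein mRNAs, which encode the ribosome of the organelle, were higher in 63 of 76 genes with a median log2 fold change of 0.27. The group passed camera at the preset correlation (adjusted p = 4.83e-10) and did not with an estimated one (adjusted p = 0.285). Small nucleolar RNA host genes were higher in 14 of 18 with a median of 0.35 (adjusted p = 0.242 with an estimated correlation), and proteasome subunits in 27 of 37 with a median of 0.15 (adjusted p = 0.339 with an estimated correlation), and both passed at the preset correlation. Scores in ZEB1 replicates 1, 2 and 3 were 0.43, 0.20 and 0.09 for mitochondrial ribosomal proteins (highest control 0.10), 0.27, 0.10 and 0.01 for proteasome subunits (highest control 0.05) and 0.38, 0.27 and 0.13 for the host genes (highest control 0.12). Replicate 3 thus lay within the control range for mitochondrial ribosomal proteins and proteasome subunits. Cytosolic ribosomal protein pseudogenes also passed it, with 8 of 14 higher (adjusted p = 0.242 with an estimated correlation), but its scores were -0.50, -0.05 and 0.25 in ZEB1 replicates 1, 2 and 3, against -0.13 to 0.11 in the controls, so the libraries disagreed in direction. Translation factors (median 0.08), tubulins (-0.10), integrins (-0.20), numbered zinc finger genes (-0.09) and solute carriers (-0.07) did not pass. None of the 9 groups passed fry (smallest adjusted p 0.114), and 0 members passed the edgeR test, where 26 mitochondrial ribosomal protein genes were higher and 2 lower at an unadjusted p under 0.05.

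Ribosomal protein and respiratory chain mRNAs, which are short and abundant, scored higher in the ZEB1 libraries. The tables argue against transcript length as the whole cause, since the lists kept 82.1% and 80.6% of their median after each library's length trend was removed, and both still passed camera at the preset correlation. With an estimated correlation neither passed after this correction (adjusted p = 0.427 for each), as on the uncorrected edgeR fit (adjusted p = 0.362 for each). Lower depth stays open. Thinning all libraries to the smallest total kept at least 103% of each median, which was meant to exclude it. That bound was wrong, because reads look clumped on few molecules in every library (see the genes at 0 below), and thinning by reads breaks such clumps, so it does not stand for a library with few molecules. Trends with length, GC content and abundance together may account for much of it, as removing them kept at most 48.7%, though both lists still passed at the preset correlation (adjusted p up to 1.31e-08, with an estimated correlation not run there), and whether those trends are technical was not tested. An effect of the ZEB1 vector in every library stays open. ZEB1 replicate 3 lay above the controls by more than their range in 0 of 2 lists. Its respiratory chain score was 0.036 below the highest control, within the control SD of 0.14, which excludes nothing in a lone library. That library also had the lowest ZEB1 level of the ZEB1 libraries, 6894 CPM.

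Secretory, mesenchymal, collagen, immediate early and protease mRNAs scored lower in the ZEB1 libraries. The length trend is argued against as the whole cause, since 5 of 5 lists kept at least 78.9% of their median after length correction and still passed camera at the preset correlation. With an estimated correlation 0 of the 5 passed after this correction (adjusted p = 0.354 to 0.427), as on the uncorrected edgeR fit (adjusted p = 0.212 to 0.362). Lower depth stays open, because thinning, after which 5 of 5 lists kept at least 69.2%, breaks clumps of reads here too. A ZEB1 vector effect in every library stays open. ZEB1 replicate 3 lay below the controls by more than their range in 2 of 5 lists, the mesenchymal list by 0.18 and the protease list by 0.16. It also lay below every control in sets that did not pass camera. These included autophagy (-0.12, lowest control -0.02), interferon-stimulated (-0.24, lowest control -0.06) and solute carrier genes (-0.09, lowest control -0.02). Heat shock genes lay above the controls (0.15, highest control 0.02). Numbered zinc finger genes, with a median log2 fold change of -0.09, scored -0.45, -0.26 and -0.13 in ZEB1 replicates 1, 2 and 3 (lowest control -0.06). Translation factors scored 0.03, 0.04 and 0.04 there (highest control 0.02). Low scores in the ZEB1 libraries were thus not particular to the called lists. The collagen score of ZEB1 replicate 3 lay within the control range. A vector effect and the other differences between the ZEB1 and control libraries cannot be told apart here, because each ZEB1 library had fewer counts than each control.

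Some genes read in every control had no count in a ZEB1 library, such as GALT and TMEM67, which were at 0 in both ZEB1 replicates 1 and 2. Among genes expected at 10 to 30 counts, the share at 0 in ZEB1 replicates 1 and 2 was at least 9.42 times that in controls thinned to the same total, which was meant to exclude depth alone. That bound was wrong, because unthinned controls at the same expected counts had 2.74% to 3.54% of genes at 0 and the ZEB1 libraries 1.39% to 2.62%, where Poisson sampling gives at most 0.000392%. Reads clumped on few molecules in every library may therefore account for it, the lowest control share being 1.04 times the highest ZEB1 share, and thinning by reads breaks such clumps. Expected counts of a control came from only the 2 other controls, which may raise its share at 0, so these shares are not fully alike. Without such a reference, 16.9% to 18.1% of counts from 1 to 10 were 1 in the controls and 16.8% to 18.6% in the ZEB1 libraries. In controls thinned to the smallest total it was 26.6% to 27.1%. Loss of different molecules in each library stays open, with 2 genes at 0 in both replicates against 0.636 for independent lists, a ratio of 3.15 (Fisher's exact test, p = 0.131), and no biological explanation was tested for these genes.

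The 6 libraries can be split into equal groups in 10 ways, too few for a share under 0.05. The real split gave 1 gene and 8 lists, and the highest of the other splits gave 0 genes and 6 lists. As many genes came from 1 of the 10 splits, and as many lists from 1 of the 10.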
